A study of Mus musculus with 5 samples.

How the data were processed

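The series holds 5 samples of mouse cerebellum, total RNA hybridised to arrays, with 1 column of values for each of E18, P7, P14, P21 and P56. Per the labels, each deposited column is the mean signal of 2 array experiments; whether these used RNA of separate animals, the array maker's scanner settings, the background correction, the normalization between arrays and how the probes were chosen are not given in the sources used here. The deposited values were read as percent: all 4485 values lie between 0.01 and 100, 420 of the 897 probes stand at exactly 100 at 1 age, 0 probes do so at 2 ages, and the other 477 have a highest value between 67.0 and below 100. This is what results when each experiment is scaled to the probe's own highest age and the experiments are then averaged, but the scaling is read from the values and not stated by the authors. The median probe has a 3.14-fold range, and neighbouring entries of the table share their highest age in 91.0% of cases, against a mean of 26.9% over 1000 shuffles, so the table is ordered by profile and may be a selection of changing probes. Counts and random lists therefore describe these probes and not the transcriptome.

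Gene symbols came from the platform's annotation, which can be old: 787 probes have 1 symbol, 16 have several and 94 have none, and only those with 1 were named. By gene identifier 784 of the 787 were found in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. No coordinates are given, since the array's genome build is not given in the sources used here.

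Values were compared as log2 of the percent, with the 20 values under 1% (in 15 probes) set to 1%, and a difference against such a value is a lower bound. A probe rose or fell when it differed by 2-fold or more. The design fixed before the data were examined had foreseen array signals with a floor at their 10th percentile, or the log2 of the ratio where values are ratios. On this scale the 10th percentile is 20.4%, which would limit every fold to 4.90, so the ratio was used; the 1% limit itself was chosen after the values were seen, and the 10th percentile floor was kept as an alternative. Fixed at the same time were the comparisons, the 2-fold rule, the 23 gene lists, the rule for named genes and the alternatives, except those named as added. Symbols with 2 probes were averaged on the log2 scale for lists.

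With 1 column per age there is no test across samples. In its place, 2 descriptions were used. First, if both experiments behind a mean lie between 0 and 100, means that differ by more than 50 points force both experiments to have moved the same way, and the counts of such probes are given; this was added after the values were seen. Second, each list's median was placed among 10000 random lists of the same size drawn from the named genes of the table, matched on mean log2 value in 10 bins, and a list stands apart under percentile 2.5 or over 97.5. On a percent scale the mean value reflects the shape of the profile, so matching can take out part of what a list shares. For lists that rose, it can instead draw genes that fell more. The matched lists for myelin had a median P56 against E18 difference of -1.93, against -1.07 for all named genes. Unmatched lists were therefore also drawn. As a measure of noise between probes, 14 genes have 2 probes. Their P56 against E18 differences were apart by a median of 0.38 (log2), against 1.70 for random pairs of probes. Of the 14 pairs, 13 had the same sign (Gnai1 was the exception) and 7 had the same highest age. Both probes of a gene were read in the same columns, so this leaves out variation between samples and arrays.

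Named genes followed a rule over probes with 1 symbol and at least 1% at both ages: the 12 largest rises and falls for P56 against E18, the 5 largest each way for each step, the 6 clearest peaks, up to 4 bounds each way, the 4 most changed genes of each list with at least 3 genes, and all genes of smaller lists. In the account of P56 against E18, Pcna, Neurod1, Peg3 and Ptgds were added after their values were seen, as an example or an exception of a list. Mki67, Pdgfra and Atp1b2, which the rule named only for steps between neighbouring ages, were also added to that account. The rule gave bounds for P56 against E18 alone, so genes under 1% in the accounts of the steps were added after their values were seen.

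The alternatives were a floor at the 25th percentile, the smallest value as floor, a pseudocount of 1%, columns divided by their medians, quantile normalization, thresholds of 3-fold and 1.5-fold, only probes at or above 1% at all ages, 1 probe per gene, unmatched random lists, P21 in place of P56, P7 in place of E18, and each age left out for steady profiles. Where a scaling or a floor moved the share of rises among changed probes by over 10 percentage points, both pairs of counts are given.

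The calculation was tested on simulated data: 897 probes in 2 experiments, each scaled to its highest age and averaged, with a noise SD of 0.3 (log2) assumed for each experiment and 200 probes changed between P7 and P14. For P56 against E18, the 2-fold rule found 48.0% of 50 probes changed by 1 on the log2 scale, 92.0% of 50 changed by 1.5, and 100% of those changed by 2 or 3, and called 0 of 697 unchanged probes. After averaging, this noise gives unchanged probes a difference SD of 0.29, below the 0.50 seen between probes of the same gene. A second simulation with a noise SD of 0.5, added after the results were seen, gave a difference SD of 0.47. There the rule found 52.0% of 50 probes changed by 1, 88.0% of 50 changed by 1.5 and 100% of those changed by 2 or 3, and called 26 of 697 unchanged probes (3.73%). Neither simulation had a difference in scale between columns, so these rates leave out errors of that kind. In the first simulation the reading of both experiments gave 0 wrong directions. That follows by construction, since both simulated experiments lay between 0 and 100. It does not test whether the deposited values are means of such experiments. Of 1000 random lists, 45 fell outside percentiles 2.5 to 97.5, and a first run with 100 other lists had 11 outside. These lists were drawn at random from the same genes as the lists they were set against, so a small share outside also follows by construction. It does not show how the percentiles behave for lists of genes that change together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.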

Results

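RNA of the mouse cerebellum was measured on arrays at 5 ages: embryonic day 18 (E18) and postnatal days 7, 14, 21 and 56 (P7, P14, P21 and P56). Per the labels, the study was meant to help find out which genes take part in building the cerebellum. Each age has 1 column of values, described as the mean signal of 2 array experiments, so there is no replicate check of any difference and no p-value is given; the number of arrays limits the precision. The table holds 897 probes, of which 787 carry a single gene symbol and together name 773 genes. Values run from 0.01 to 100 and were read as the percent of each probe's own highest age in each experiment, averaged over the 2 experiments. A value can thus be set against other ages of the same probe but not against another probe. The median value fell from 84.5% at E18 and 82.8% at P7 to 55.5% at P14, 42.3% at P21 and 42.0% at P56. A probe is said to have risen or fallen only when it differed by 2-fold or more.

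The adult cerebellum (P56) was compared with the embryonic one (E18). Most measured genes in the lists of mature neurons and myelin rose, and most in those of dividing cells and immature neurons fell. Mobp, a myelin protein gene, rose 55.9-fold, from 1.08% to 60.4%, and Pvalb, which encodes the calcium-binding protein parvalbumin of Purkinje cells and interneurons, rose 40.8-fold. Ccna2, the cyclin A2 gene, fell 64.3-fold, from 88.2% to 1.37%, and Prc1, which encodes a protein of the mitotic spindle midzone, fell 64.1-fold. In all, 203 probes rose, 471 fell and 223 stayed within 2-fold. If each experiment lies between 0 and 100, both must have moved the same way for 168 of the probes that rose and 386 of those that fell. The median difference over all probes was -1.07 (log2), and dividing each column by its median, which moves that median by 1.01, gave 272 probes higher and 147 lower in place of 203 and 471. Quantile normalization gave 246 and 206, so whether falls or rises were more numerous depends on the scale between columns.

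**Figure D1:**
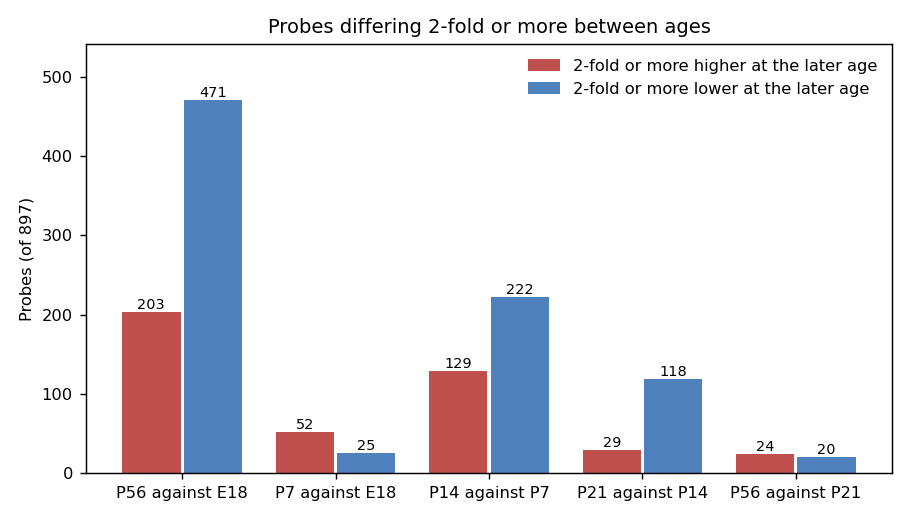
Number of probes (of 897) that were 2-fold or more higher (red) or lower (blue) at the later age, for P56 against E18 and for each step between neighbouring ages. Of the steps, P7 to P14 holds the highest counts (129 higher and 222 lower) and P21 to P56 the lowest (24 and 20); dividing columns by their medians turns the majority from lower to higher for P56 against E18 (272 against 147), for P14 against P7 (238 against 105) and for P21 against P14 (61 against 51).

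Among probes at or above 1% at both ages, after Mobp and Pvalb, Syt2, a synaptotagmin gene of synaptic vesicles, rose 33.6-fold. Hs3st1, a heparan sulfate sulfotransferase gene, rose 28.3-fold, and Ntsr2, a neurotensin receptor gene, rose 27.5-fold. Sowaha rose 24.2-fold, and Atp2a3, which encodes a calcium pump of the endoplasmic reticulum, rose 23.7-fold on one of its 2 probes; the other was under 1% at E18. Kcnj9, a potassium channel gene, rose 21.8-fold and Hsd11b1, which encodes an enzyme that regenerates active glucocorticoid, rose 19.7-fold. Agt, the angiotensinogen gene, rose 16.4-fold, S100b, a calcium-binding protein gene of glia, 16.1-fold, and Nptx1, a neuronal pentraxin gene, 11.5-fold. Other genes were under 1% at E18 and have only a bound: Dao, the D-amino acid oxidase gene, and Kcna1, a voltage-gated potassium channel gene, were both at least 100-fold higher at P56. Gabra6 and Gabrd, which encode GABA-A receptor subunits of granule cells, were at least 99.8-fold and at least 79.5-fold higher.

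Among probes at or above 1% at both ages, after Ccna2 and Prc1, D430019H16Rik fell 63.7-fold, and the transcription factor genes Sox11 and Sox4 fell 52.2-fold and 39.1-fold. The Myc family genes Mycl and Mycn fell 43.7-fold and 40.7-fold. Cdk1, the kinase that drives mitosis, fell 39.4-fold, Cks1b 32.4-fold and Mcm3, a subunit of the replicative helicase, 30.2-fold. Nt5dc2 fell 31.1-fold and Sinhcaf, a gene of the Sin3 histone deacetylase complex, 28.8-fold. Among genes under 1% at P56, Hmgb2 was at least 83.4-fold lower than at E18, Ncaph, a condensin subunit gene, at least 69.7-fold, Igfbpl1 at least 61.0-fold and Ccnd2, the cyclin D2 gene, at least 49.5-fold.

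All 35 measured genes of cell cycle and DNA replication fell from E18 to P56, with a median of -2.91 (log2), which is -1.84 relative to the median gene. Beside Hmgb2, Ccna2, Ccnd2 and Cdk1, the list holds Mki67, a marker of dividing cells, which fell 26.5-fold, and Pcna, the replication clamp gene, which fell 4.15-fold. Among 10000 random lists of genes with the same mean values its median lay at percentile 3.98 (53.3 with a floor at the 10th percentile of values and 93.5 with one at the 25th), and among unmatched random lists at percentile 0. Of the 35 genes, 28 fell with columns divided by their medians, 28 with quantile normalization and 28 with the floor at the 25th percentile. Of the 8 measured genes of granule cell progenitors and Hedgehog signalling, 2 of them cyclins shared with the cell cycle list, 7 fell. Mycn and Ccnd2 led, and Nhlh1, a transcription factor gene, fell 5.93-fold and Ccnd1 4.21-fold; Neurod1, another transcription factor gene, stood at 56.7% at E18 and 40.6% at P56. The list's median of -1.94 lay at percentile 36.9 of matched lists and 1.40 of unmatched ones. With columns divided by their medians 4 of the 8 fell, and with quantile normalization 5. Of 16 genes of immature neurons, axon growth and migration 14 fell and 1 rose, with a median of -2.26 at percentile 0.03. With columns divided by their medians 9 of the 16 fell, and with quantile normalization 10. Igfbpl1, Sox11, Sox4 and Dpysl3, a collapsin response mediator gene that fell 28.6-fold, changed most, and Peg3, an imprinted gene, was the one that rose, 3.43-fold.

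Lists of mature neurons moved the other way. Of 10 measured genes of mature granule cells 8 rose, with a median of 2.32 (percentile 100). Gabra6, Gabrd and Kcnj9 led this list, and Etv1, a transcription factor gene, rose 10.3-fold. All 9 genes of Purkinje cells rose, with a median of 1.88 (percentile 99.9); after Pvalb, Atp2a3 and Nptx1, Kcnma1, a calcium-activated potassium channel gene, rose 4.20-fold. All 9 genes of voltage-gated and potassium channels and ion pumps rose, with a median of 3.03 (percentile 99.99); Scn1a, a sodium channel gene, rose 9.79-fold. All 5 receptor genes rose, with a median of 2.86 (percentile 99.4): besides the granule cell subunits, Grin2c, an NMDA receptor subunit gene, rose 7.24-fold and Glrb, a glycine receptor subunit gene, 3.49-fold. Of 12 genes of calcium and calmodulin signalling 10 rose, with a median of 1.69 (percentile 99.99). In this list Vsnl1, a neuronal calcium sensor gene, rose 5.40-fold and Ryr2 4.90-fold. These lists share members: 7 of the 10 granule cell genes, 4 of the 9 Purkinje cell genes, 3 of the 5 receptor genes, 5 of the 9 channel genes and 4 of the 12 calcium signalling genes are also in another list.

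Of 17 genes of the synaptic vesicle and release machinery 11 rose and 2 fell, with a median of 1.26 (percentile 99.97). After Syt2, Snap25, the gene of a membrane fusion protein of nerve terminals, rose 5.32-fold. The 2 that fell were Stx1a, the syntaxin 1A gene of the same fusion complex, from 100% at E18 to 3.66% (27.3-fold), and Syt5, another synaptotagmin gene, from 100% to 7.39% (13.5-fold).

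Glial lists rose with exceptions. Of 10 measured oligodendrocyte and myelin genes 7 rose and 1 fell, with a median of 1.89 (percentile 99.7). With a floor at the 25th percentile of values 2 of the 10 rose and 0 fell, with a median of 0.55 (percentile 99.7). Mag and Mog, which encode proteins of the myelin sheath, were under 1% at E18 and at least 54.7-fold and at least 46.8-fold higher at P56. Car2, the carbonic anhydrase 2 gene, rose 5.06-fold, and Pdgfra, a receptor gene of oligodendrocyte progenitors, fell 3.79-fold. Of 12 genes of astrocytes and Bergmann glia 8 rose and 3 fell, with a median of 1.85 (percentile 99.8). S100b rose most, Aqp4, the main water channel gene of astrocytes, rose 6.86-fold and Atp1b2, a sodium pump subunit gene, 5.48-fold. In contrast, Tnc, the tenascin C gene, fell 10.1-fold and Id3 fell 5.69-fold.

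**Figure D2:**
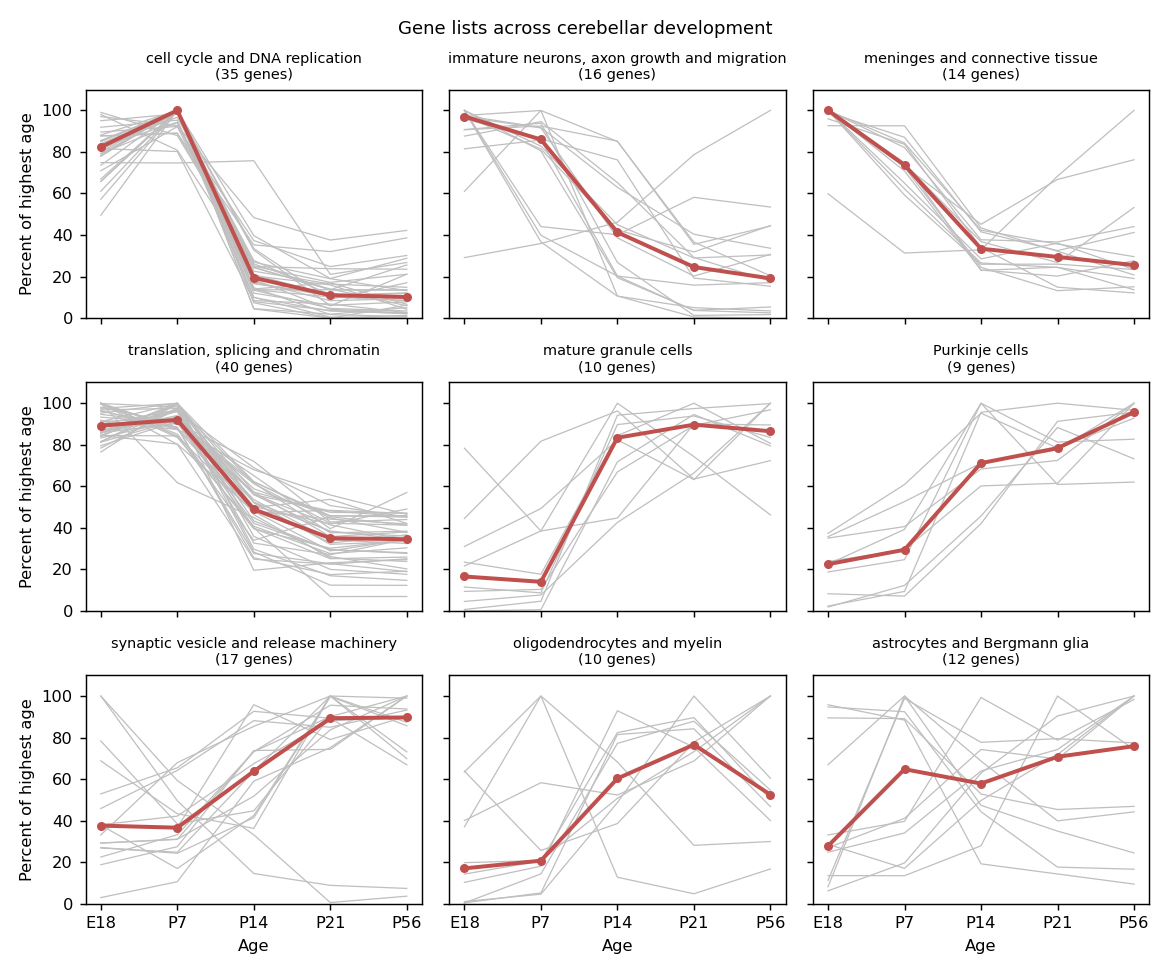
Value in percent (vertical axis) at the 5 ages (horizontal axis, evenly spaced and not to scale) for 9 gene lists. Percent was read as relative to a probe's highest age in each experiment, then averaged, so a highest mean can lie below 100. Grey lines are genes and the red line with points is the median over the list. The median of the cell cycle list goes from 82.4% at E18 and 100% at P7 to 19.4% at P14 and 10.2% at P56, and that of mature granule cells from 14.0% at P7 to 83.4% at P14.

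The lists of translation, splicing and chromatin, of ribosomal proteins and of cholesterol synthesis were lower in the adult, with medians of -0.22, -0.33 and -0.21 relative to the median gene. Of 40 genes of translation, splicing and chromatin 33 fell and none rose, with a median of -1.29 (percentile 2.86); Hmgb3, a chromatin protein gene, fell 13.4-fold, and Kpna2, Hmgn2 and Snrpg fell 6.60-fold, 5.81-fold and 5.53-fold. With columns divided by their medians 8 of the 40 fell. Of 5 ribosomal protein genes 4 fell, Rpl10a by the most (3.25-fold), with Rps27l at 3.14-fold, Rpl36 at 2.64-fold and Rpl7 at 2.21-fold; the median was -1.40 (percentile 1.37 of matched and 19.96 of unmatched lists), and 0 of the 5 fell with columns divided by their medians. All 4 cholesterol synthesis genes fell: Sqle, which encodes squalene epoxidase, 4.22-fold, Fdft1 2.61-fold, Fdps 2.27-fold and Idi1 2.13-fold. Their median of -1.29 lay at percentile 1.53 of matched and 30.4 of unmatched lists, and 1 of the 4 fell with columns divided by their medians. Of 3 genes of glycolysis and the citrate cycle 1 rose, the phosphofructokinase gene Pfkm, by 3.79-fold, while Pfkl went from 100% to 65.3% and Slc2a1, a glucose transporter gene, from 63.5% to 87.6% (median 0.46, percentile 85.8). The 3 immediate early genes rose, Nr4a1 5.10-fold, Egr1 3.97-fold and Dusp1 2.61-fold (median 1.99, percentile 96.5).

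Markers of other cells that the tissue could hold also moved with age. Of 14 genes of meninges and connective tissue 11 fell and none rose, with a median of -1.97 (percentile 0.65): Nid1, a basement membrane gene, fell 7.90-fold, Serpinh1, the collagen chaperone gene, 7.33-fold, and the collagen genes Col3a1 and Col1a2 6.63-fold and 5.24-fold, while Ptgds, the prostaglandin D synthase gene, went from 59.9% to 100%. Of 5 endothelial and pericyte genes 3 fell, Col4a1 7.66-fold, Col4a2 4.05-fold and Kdr, a VEGF receptor gene, 3.60-fold, while Pltp went from 50.6% to 100% (median -1.85, percentile 0.64 of matched and 5.86 of unmatched lists). With columns divided by their medians 2 of these 5 were higher and 2 lower, and of the 14 meningeal genes 1, Ptgds, was higher and 7 were lower. Of 2 choroid plexus genes, Igfbp2 fell 3.62-fold and Ttr, the transthyretin gene, went from 100% at E18 to 17.1% at P14 and 62.9% at P56. Of 2 microglial and immune genes, Ctss, the cathepsin S gene, rose 3.36-fold and Laptm5 went from 80.4% to 48.9%. The single gene of the erythroid list, Ank1, which neurons also express, rose 6.27-fold. Of 3 genes in the list for forebrain or brainstem neurons, Sst, the somatostatin gene, fell 11.0-fold, Penk, the proenkephalin gene, rose 3.44-fold and Npy, the neuropeptide Y gene, went from 47.1% to 83.4% (median 0.82, percentile 86.9). Cells of the cerebellum itself may express these genes too, and values of whole tissue do not show which cells they come from. No gene of the respiratory chain list was among the named probes.

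**Figure D3:**
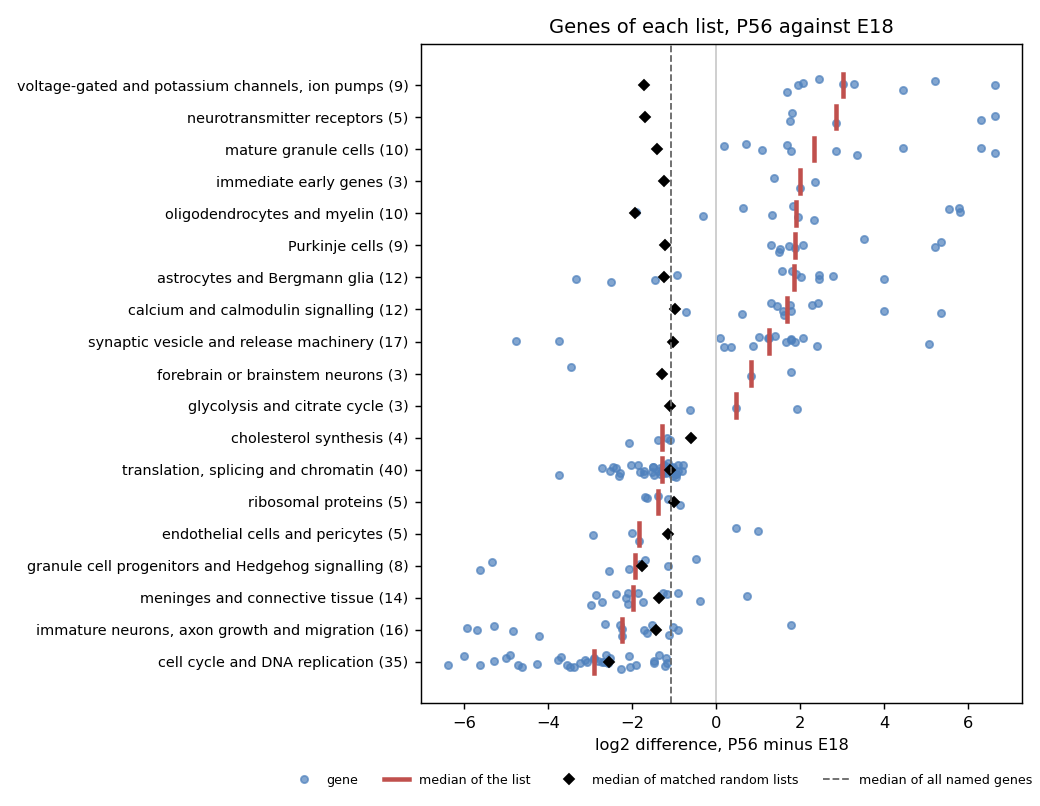
Difference between P56 and E18 on the log2 scale (horizontal axis) for each gene (blue points) of the 19 lists with at least 3 measured genes, with the median of the list (red bar), the median of its matched random lists (black diamond) and the median of all named genes (dashed line, -1.07). List medians run from -2.91 for the cell cycle to 3.03 for channels and pumps, and none changes sign under either scaling of the columns.

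From E18 to P7 few probes changed: 52 rose, 25 fell and 820 stayed within 2-fold. With a floor at the 10th percentile of values 24 rose and 21 fell, and with one at the 25th percentile 13 rose and 19 fell, so the majority of rises depends on low values. Among probes at or above 1% at both ages, Gfap, the intermediate filament gene of astrocytes, rose 12.2-fold from 8.17% to its highest value, Agt rose 10.9-fold and Aqp4 8.76-fold. From under 1% at E18, one of the 2 probes of Atp2a3 was at least 18.7-fold higher and Mag at least 14.4-fold. Mobp stood at 1.08% and 4.63% (4.29-fold), a rise that turned to -0.77 (log2) with quantile normalization, and Foxn2, a forkhead gene, rose 4.21-fold. The largest falls were in Nefm, a neurofilament gene (3.24-fold), Sfrp2, a secreted Wnt antagonist gene (2.96-fold), Mfap2, a gene of extracellular microfibrils (2.91-fold), Dpysl3 (2.73-fold) and Runx1t1 (2.69-fold). Lists that stood above their random lists were oligodendrocytes and myelin (median 0.73, 4 of 10 rose and 1 fell, percentile 99.8), channels and pumps (0.74, 3 of 9 rose, 99.7), Purkinje cells (0.56, 2 of 9 rose, 99.0) and astrocytes (0.36, 3 of 12 rose, 99.0); with quantile normalization these lists lay at percentiles 59.2, 82.7, 83.6 and 68.3 and no longer stood apart. Meningeal genes had a median of -0.44 at percentile 0.015 with none past 2-fold, and the 3 genes of glycolysis -0.76 at percentile 0.10 with 1 fallen. The cell cycle list had a median of 0.25 (percentile 90.2), and 1 of its 35 genes rose, Ccnd2, from 49.5% to 100%. With quantile normalization that list stood apart, with a median of 0.65 at percentile 99.9, and so did the progenitor list, with 0.79 at percentile 99.6. Quantile normalization gave 44 probes higher and 59 lower in place of 52 and 25, and turned the medians of the granule cell (0.40), synaptic (0.07), receptor (0.43) and ribosomal (-0.03) lists to the other sign. Both experiments must have moved the same way for 12 of the 52 and 18 of the 25, which include Gfap and Aqp4 but not Agt, Mobp or Foxn2.

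From P7 to P14 the largest number of probes changed of any step, with 129 higher and 222 lower. Division genes fell together: 33 of the 35 cell cycle genes, with a median of -2.36 (percentile 0), led by Tk1, the thymidine kinase 1 gene, from 100% to 4.43% (22.6-fold), and Cdc20, an activator gene of the anaphase-promoting complex (21.8-fold). Kifc5b, a kinesin gene, fell 14.3-fold, Ccna2 13.5-fold and Mki67 12.6-fold. Genes of mature granule cells rose, 7 of 10 with a median of 2.36 (percentile 100). Gabrd was at least 71.8-fold higher, and Gabra6 rose 20.2-fold from 4.67% to 94.2%. Mog rose 15.6-fold from 5.22% to 81.4%, Hs3st1 11.5-fold and Hsd11b1 10.8-fold. One probe of Atp2a3 rose 11.0-fold, and the other went from 18.7% to 26.3%. Genes also rose in the lists of receptors (3 of 5, median 3.36), oligodendrocytes and myelin (6 of 10, with 1 fallen, 1.64), Purkinje cells (6 of 9, 1.35), calcium signalling (8 of 12, with 1 fallen, 1.20), channels and pumps (6 of 9, 1.05) and synaptic vesicles (7 of 17, with 1 fallen, 0.76), each of them standing above its random lists. The receptor genes that rose were Gabra6, Gabrd and Grin2c, which are all in the granule cell list too. The 3 immediate early genes had a median of 1.81 with 2 risen (percentile 99.7), and of the 40 translation, splicing and chromatin genes 16 fell (median -0.87, percentile 0.04). Of the 14 meningeal genes 11 fell (median -1.15, percentile 3.04; 2.18 with quantile normalization). The median difference over all probes was -0.58, and dividing columns by their medians gave 238 higher and 105 lower, and quantile normalization 224 and 164, in place of 129 and 222.

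From P14 to P21 29 probes rose and 118 fell. Many of the falls lie at low values: a floor at the 10th percentile gave 27 higher and 63 lower, and one at the 25th percentile 22 and 31. Genes of immature neurons fell in 9 of 16 cases, with a median of -1.12 (percentile 0.03), led by Sox11 from 26.8% to 1.32% (20.3-fold). Among probes at or above 1% at both ages, D430019H16Rik fell 15.8-fold, Mycn 11.5-fold, Mycl 10.7-fold and Hmgb2, a chromatin protein gene, 8.68-fold. Among genes under 1% at P21, Stx1a stood at 33.2% at P14 and was at least 33.2-fold lower. Igfbpl1, Ncaph and Ccnd2 went from 10.68%, 10.5% and 10.05% to under 1%. The progenitor list had a median of -1.12 with 4 of 8 fallen (percentile 2.0), and 15 of the 35 cell cycle genes fell (median -0.92, percentile 7.42; with quantile normalization the median was 0.06 and the percentile 22.8). The largest rises were in Gh, the growth hormone gene, from 22.2% to 100% (4.51-fold), one probe of Atp2a3 (3.80-fold), Atp1b2 (3.58-fold), Npy (3.15-fold) and Kcnn1, a calcium-activated potassium channel gene (2.91-fold). Synaptic vesicle genes had a median of 0.35 with 4 of 17 risen and 1 fallen (percentile 100), channels and pumps 0.53 with 2 of 9 risen (percentile 99.98), and granule cell and myelin lists 0.15 each (percentiles 99.2 and 98.9). The lists of calcium signalling (0.19, percentile 99.8) and glycolysis (0.38, percentile 98.8) also stood high with no gene past 2-fold. With quantile normalization the granule cell, myelin, channel, calcium and glycolysis lists no longer stood apart at this step, at percentiles 59.3, 67.3, 94.7, 78.3 and 89.4, while the meningeal list, at -0.16 (percentile 84.8), changed sign to 0.43 and stood above its random lists (percentile 98.6). For 18 of the 29 and 15 of the 118 both experiments must have moved the same way. None of the named falls is among them, as all of these genes were under 50% at P14. Dividing columns by their medians gave 61 higher and 51 lower, and quantile normalization 57 and 40, in place of 29 and 118.

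From P21 to P56 24 probes rose and 20 fell, and 853 stayed within 2-fold; with a floor at the 10th percentile 13 rose and 10 fell, and with one at the 25th percentile 7 and 4. Among probes at or above 1% at both ages, Smoc1, a gene of an extracellular calcium-binding protein, rose 6.13-fold from 2.88%, Tubg2, a gamma tubulin gene, 3.95-fold, Lig1, the DNA ligase I gene, 3.57-fold, Timeless, a replication fork gene, 3.50-fold and Pdgfra 3.48-fold. Gh fell 3.94-fold back to 25.4%, Cenpa, the centromeric histone gene, fell 3.76-fold, Fxyd7, a sodium pump regulator gene, 3.19-fold, Adam19, a metalloprotease gene, 3.08-fold and Canx, the calnexin gene, 2.57-fold. Of the lists, cholesterol synthesis (median -0.56, percentile 0.21) and endothelial cells and pericytes (-0.44, percentile 1.58) lay below their random lists with no gene past 2-fold. Of the 35 cell cycle genes 3 rose and 4 fell. Both experiments must have moved the same way for 6 of the 24 and 3 of the 20, which include Tubg2, Gh and Fxyd7 among the named genes.

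Over all ages, 842 probes differed by 2-fold or more between their highest and lowest age. Of these 304 were highest at E18, 273 at P7, 68 at P14, 71 at P21 and 126 at P56. In the cell cycle list 30 of 35 genes were highest at P7 and 4 at E18, in the meningeal list 13 of 14 at E18, and all 5 ribosomal protein genes at E18. Among myelin genes, 4 of 10 were highest at P21, including Mobp (100% at P21 and 60.4% at P56), Mog (84.2% and 46.8%) and Mag (87.9% and 54.7%). Values rose at every step for 65 probes and fell at every step for 112, against 7.02 each if the order of the ages were random. All probes share the same 5 columns and their scale, so 7.02 is a reference and not a test. A highest value at P7, P14 or P21 that was 2-fold or more above both E18 and P56 occurred in 16 probes. The clearest were Slc29a1, a nucleoside transporter gene, at P7 (100% against 28.0% at E18 and 8.63% at P56), Foxn2 at P14 (100% against 13.1% and 33.3%), Sfrp1, a Wnt antagonist gene, at P7 (100% against 34.7% and 10.7%), Gh at P21 (100% against 36.2% and 25.4%), Cd9, a tetraspanin gene, at P7 (100% against 37.1% and 30.0%) and Ltbp2, a gene of the latent TGF-beta binding protein family, at P14 (100% against 17.8% and 39.0%). With columns divided by their medians the number of probes highest at E18 was 98 and at P7 102, in place of 304 and 273, and 109 rose and 27 fell at every step.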

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

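The 10th percentile floor, floors with unmatched random lists and the counts of probes whose experiments must both have moved the same way were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each age has 1 column and no test was run. With no replicates, no signal over background and 1 value per age, differences near 2-fold are the least certain. Each of the 13 list medians that stood apart for P56 against E18 kept its sign with columns divided by their medians, with quantile normalization, with P21 in place of P56 and with P7 in place of E18. The floors and unmatched random lists cannot change a sign, and 1 probe per gene changed 1 list median. Probe counts stayed within 1.5 times with the smallest value as floor, with a pseudocount, with 1 probe per gene and with only probes at or above 1% at all ages.

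Dividing columns by their medians gave, for P56 against E18, 147 lower; for P14 against P7, 238 higher and 105 lower; for P21 against P14, 61 higher and 51 lower. With it 98 probes were highest at E18, 102 at P7, 38 at P14 and 110 at P21, and 109 rose and 27 fell steadily. Quantile normalization gave 206 lower for P56 against E18, 59 lower for P7 against E18, 224 higher for P14 against P7, and 57 higher and 40 lower for P21 against P14, with 176 highest at E18, 171 at P7, 35 steady rises and 31 steady falls. Dividing by medians multiplies each column by 1 factor, which raises the columns from P14 on relative to E18 and P7. By construction this takes probes out of the falls and brings others into the rises. Quantile normalization also changes values within a column, and the causes of its 59 for P7 against E18 and of its 35 steady rises, in place of 65, were not tested.

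With a 3-fold threshold, higher and lower counts were 135 and 234 for P56 against E18, 20 and 1 for P7 against E18, 53 and 104 for P14 against P7, 4 and 38 for P21 against P14, and 9 and 4 for P56 against P21. With 1.5-fold they were 129 and 81 for P7 against E18, 213 and 447 for P14 against P7, 63 and 311 for P21 against P14, and 82 and 78 for P56 against P21. These thresholds change the counts by their construction.

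The 25th percentile floor, which sets all lower values to 35.8%, gave 13 higher and 19 lower for P7 against E18, 22 higher and 31 lower for P21 against P14, 7 higher and 4 lower for P56 against P21, 21 steady rises and 51 steady falls. The 10th percentile floor gave 24 higher and 21 lower for P7 against E18, 27 higher and 63 lower for P21 against P14, and 13 higher and 10 lower for P56 against P21. Both experiments must have moved the same way for 12 higher (P7 against E18), 70 higher (P14 against P7), 18 higher and 15 lower (P21 against P14), and 6 higher and 3 lower (P56 against P21). Steady falls numbered 230 leaving out E18, 215 leaving out P7, 228 leaving out P21 and 233 leaving out P56, and steady rises 104 leaving out P14, 115 leaving out P21 and 100 leaving out P56, since fewer steps have to go one way.

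Against unmatched random lists the cell cycle (-2.91), progenitor (-1.94) and immediate early (1.99) lists stood apart, and the ribosomal (-1.40), cholesterol (-1.29) and endothelial (-1.85) lists no longer did. The endothelial list (-1.26) also did not with the 25th percentile floor, nor cholesterol (-0.57) with quantile normalization, while the translation, splicing and chromatin list (-1.29) did with the 10th percentile floor. With P21 in place of P56, translation (-1.33) stood apart and cholesterol (-0.91), endothelial (-1.41) and meningeal (-1.75) genes did not. With P7 in place of E18, the cell cycle (-3.29), translation (-1.41) and immediate early (1.97) lists stood apart, and astrocytes (0.46), ribosomal (-1.39), cholesterol (-1.17) and meningeal (-1.41) genes did not; the cause was not tested. Of the 133 values of named genes, 78 moved by 1.5 times or more with columns divided by their medians, 66 with quantile normalization, 93 with the 25th and 74 with the 10th percentile floor. Of the 127 that were 2-fold or more apart, 116, 120, 103 and 116 remained so in the same direction, in that order. One changed direction: Mobp for P7 against E18, at -0.77 with quantile normalization.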

Other observations

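The tests on probes with a highest value below 100, with floors among unmatched random lists and on the meningeal list's rising members and percentile were chosen after the result was seen, and the genes of the next paragraph were picked after their values were seen; the other tests were chosen before the list results were computed, when the column medians and part of the table had been looked at.

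Some neurofilament and tubulin genes, picked after their values were seen, differed in direction between E18 and P56. Among neurofilament genes, Nefm went from 100% to 32.7%, a difference of -1.61 on the log2 scale, and Nefh from 16.1% to 100%, a difference of 2.63. Among tubulin genes, Tubb5 (-1.54) and Tuba3b (-1.79) fell, and Tubb4a (1.27) and Tuba4a (2.70) rose, whereas Tubg2 stood at 68.0% and 69.3%. The genes that fell or rose kept their signs with columns divided by their medians and with quantile normalization. With the former, however, Nefm (-0.60), Tubb5 (-0.53) and Tuba3b (-0.78) were within 2-fold, while Nefh, Tubb4a and Tuba4a still rose. Tubb5 (-0.79) was also within 2-fold with quantile normalization. Whether the neurofilament and tubulin genes with lower values fell thus depends on the scale between columns. The transcription factor genes Ebf1, Ebf2 and both probes of Ebf3 were at 100% at E18 and at 34.1%, 26.7%, 4.58% and 8.85% at P56. Notch1 and Notch3 went from 100% to 11.5% and 28.2%, and En1, a patterning gene of the midbrain and hindbrain, from 100% to 22.4%. Of these genes, Ebf1 (-0.54), Ebf2 (-0.90) and Notch3 (-0.82) were within 2-fold with columns divided by their medians. Ebf1 (-0.96) was so with quantile normalization too. Both probes of Ebf3, Notch1 and En1 still fell under either scaling. Cdkn1c, the gene of a cyclin-dependent kinase inhibitor, was already down to 43.1% at P7 and 7.20% at P14, whereas 30 of the 35 cell cycle genes were at their highest at P7. Cdkn1a, the gene of a related inhibitor, was at 100% at P14 on both of its probes and at 31.8% and 30.7% at P56. Gh reached 100% at P21 and stayed between 22.2% and 36.2% at the other ages. Actb, often used as a control gene, went from 84.5% to 35.1%, a difference of -1.27 on the log2 scale that was -0.26 with columns divided by their medians.

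The scale of the table can be partly read from its values. If the values had been scaled once, after averaging, every probe would reach 100, but 477 probes have a highest value below 100, which argues against it. If each experiment was scaled to its own highest age, experiments that peak at different ages give means of at least 50 at both of those ages. None of the 477 probes (0) has a second-highest value under 50, whereas 23 of the 420 that reach 100 do, so the scaling of each experiment before averaging remains a candidate explanation, as a hypothesis found on the same table.

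Cell cycle genes were lower at P56 than at E18. A difference in scale between whole columns as the only cause is argued against by the list's median of -1.90 after each column was divided by its median. The make-up of the table, in which many genes fall, is argued against by percentile 0 among unmatched random lists. The percentile was also 0 with a floor at the 10th percentile of values. With a floor at the 25th percentile, which caps the largest falls, it was 3.58. There the list did not stand apart, so that setting does not argue against the make-up of the table. Among matched lists the percentile was 3.98, and 53.3 and 93.5 with those floors, so the position among matched lists depends on low values. Age may account for the pattern, as a hypothesis that was not tested, since a single sample stands for each age.

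Meningeal and connective tissue genes were lower at P56 than at E18. With each column divided by its median the list's median was -0.96, which lies between the bounds set for and against a difference in scale; a scale shared by all genes as the whole cause is argued against by percentile 0.15 of the list among unmatched random lists. Whether a smaller share of meningeal tissue in older samples is the whole cause stays open. Such a loss would lower every member that only this tissue expresses; 11 of 14 members fell, 0 rose 2-fold or more, and Ptgds, picked after its value was seen, went from 59.9% to 100%. Ptgds was 2-fold or more higher with columns divided by their medians and with quantile normalization. The members' differences had an SD of 1.03, above the 0.50 of single probes of the same gene, but other cells express several of them, Ptgds included. Lower expression per cell with age stays open and untested.

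Another hypothesis was that cell cycle genes hold their E18 level at P7 more than other genes that fall by P56. Their median P7 against E18 difference was 0.25, against -0.04 for random lists of the 408 genes that were 2-fold or more lower at P56, at percentile 100, which is consistent with it. The 7 falling progenitor genes, 2 of them in both lists, had a median of 0.38 at percentile 99.8 in the same kind of lists, and the 11 falling meningeal genes one of -0.42 at percentile 0.35.

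The hypothesis that oligodendrocyte and myelin genes gain more from P14 to P56 than other rising genes was not borne out. The 7 rising genes of the list had a median P56 against P14 difference of -0.50, against 0.36 for random lists of the 170 genes that rose by P56, at percentile 0.035. The 7 went both ways: Car2, Qdpr and Mobp were higher at P56 than at P14, and Mag, Cldn11, Mog and Gsn were lower.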
